A study of Mus musculus with 6 samples.

How the data were processed

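Basal cells of the mouse mammary epithelium were profiled on 6 whole-transcript expression arrays, 1 per biological replicate. Per the labels, the cells came from virgin females aged 8 to 14 weeks. There were 3 wild type arrays and 3 arrays of mice lacking Trp53 and Cdkn2a. The glands were digested to single cells, most blood and endothelial cells were removed with beads against CD45, CD31 and TER119, and basal cells were sorted by flow cytometry after staining that included CD49f and CD24. RNA was extracted from the sorted cells, amplified with a whole-transcript Pico kit and labelled with biotin, per the labels' protocols.

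The deposited values are log2 expression values per probe set. Per the submitters' processing notes they were made with RMA, which corrects background, normalizes arrays to each other and summarizes probes, and Transcriptome Analysis Console 4.0 was used. Array scan dates and batches were not used here. No array held the same values as another. Medians over all rows lay between 5.22 and 5.39, and Pearson correlations between arrays, across genes, between 0.971 and 0.988. An array has no read depth, and the number of arrays limits the precision.

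The deposited table held 41345 rows. The annotation gave 1 gene symbol for 23521 rows and several for 1814, and 16010 rows were unnamed here. Rows with exactly 1 symbol were used, and of several rows of a gene the one with the highest mean over all arrays was kept, which applied to 1082 genes and left 22180 genes. Of their gene identifiers 21994 were found in a RefSeq gene table of assembly GRCm38.p6, used only for names and for which genes are neighbours. Trp53 had no row under its own symbol in the annotation and was not analysed here. The position of the Cdkn2a probes relative to the deleted part was not given in the sources used here.

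Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-dependent prior), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are knockout minus wild type, with the moderated standard error. Before the data were examined, 43 gene lists of pathways and cell types were fixed. Of their 1166 entries 1053 were measured, 22 of them through an older symbol, and 42 lists with at least 5 measured genes were tested with limma's camera at a preset inter-gene correlation of 0.01. Beside it stand camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance and, in its mixed form, whether they change in either direction. An exact permutation test of 3 arrays against 3 cannot give a p under 0.1.

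The rule for named genes, also fixed beforehand, took Trp53, Cdkn2a and its neighbour Cdkn2b. It added the 10 largest rises and 10 largest falls past the threshold with groups that do not overlap, filled where too few passed with the genes of smallest p whose groups do not overlap, given as values that did not pass. Predicted genes without an assigned name were skipped, 4 of them among the falls and 0 among the rises. In each list the 4 members of smallest p could be named, and in a list past the set test any member past the threshold.

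The wild type and knockout arrays carry the same replicate numbers. Deviations from the group means correlated between same-numbered arrays with r of 0.121, 0.25 and 0.127 across genes. No label says what a number shares, and 3 arrays per genotype allow few matchings, so these values cannot establish pairing. Same-numbered arrays were treated as possible pairs only. Wild type replicate 1 correlated slightly more with knockout replicate 3, at 0.13. The fit without the pairing was fixed as the main one, and the fit with replicate as a block was run beside it.

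The fit and the list test were tested on simulated arrays with the means and residual spreads of the 22180 genes, in 20 runs with 200 changed genes each. At a log2 change of 0.5 the fit recovered 2.9% of changed genes, at 1 it recovered 47.2%, at 2 it recovered 88.8% and at 3 it recovered 97.6%, with 4.7 false calls per run on average. A list shifted by 0.5 passed camera in 20 of 20 runs at the preset correlation and in 19 with an estimated correlation. All sizes of change were mixed in each run, so strongly changed genes loosened the adjusted threshold for the others. The recovered shares hold for that mix and would be lower with fewer changed genes. Genes in the simulation varied independently, which real genes do not.

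Alternatives changed the prior, array weights, normalization, centring, the filter on dim genes, the choice of rows, the pairing, the thresholds and the list test, and left out each array in turn. Figures were drawn with matplotlib 3.10.9.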

Results

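The study compared gene expression in freshly sorted mammary basal cells, the outer epithelial layer that holds myoepithelial cells and cells with regenerative capacity, between wild type mice and mice without Trp53 and Cdkn2a. Trp53 encodes p53, a transcription factor activated by damage and other stresses. Cdkn2a encodes p16Ink4a, an inhibitor of cyclin-dependent kinases, and p19Arf, which restrains the p53 antagonist Mdm2. Each genotype had 3 biological replicates, with 1 array each. The question the design poses is which transcripts differ between the genotypes.

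Cdkn2a probe signal differed between the groups by less than the spread of the arrays. It was 6.25 ± 0.356 (SD, n = 3) on the log2 scale in wild type cells and 6.32 ± 0.070 in knockout cells, a log2 fold change of 0.07 with a standard error of 0.197 (limma adjusted p = 1.0). The single wild type arrays read 6.42, 5.84 and 6.48 and the knockout arrays 6.25, 6.31 and 6.39. The sign of this value turned to -0.13 without wild type replicate 2. Where the probes lie relative to the deletion is not known here and Trp53 was not analysed here, so neither gene checked the labels. Cdkn2b, the neighbouring gene of Cdkn2a, which encodes the kinase inhibitor p15Ink4b, had a log2 fold change of 0.44 with a standard error of 0.156, and all 3 knockout arrays lay above all wild type arrays, but it did not pass (limma adjusted p = 1.0).

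**Figure D1:**
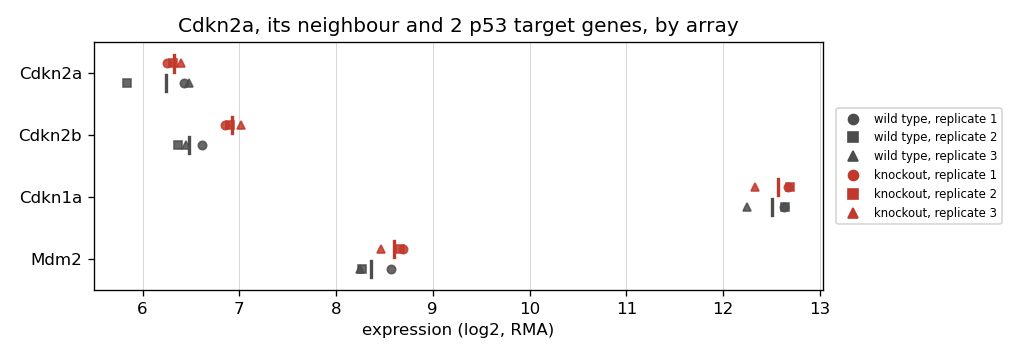
Log2 expression of Cdkn2a, Cdkn2b, Cdkn1a and Mdm2 on each array, with wild type in grey, knockout in red, a marker shape per replicate number and a bar at each group mean. Cdkn2b is the one of these 4 genes whose knockout arrays all lie above the wild type arrays.

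No single gene passed the threshold in either direction. With limma, 0 of 22180 genes were higher and 0 were lower in the knockout at an adjusted p under 0.05, and the smallest adjusted p was 0.818. At an unadjusted p under 0.05 there were 357 higher and 379 lower genes, 736 in all, where chance alone gives 1109. With replicate as a block these numbers were 527 and 585, and 0 genes passed. All knockout arrays lay above all wild type arrays for 805 genes and below for 899, together 7.68% of genes, where chance gives 10%. The median standard error of a log2 fold change was 0.173.

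Canonical p53 target genes did not pass as a list. Of 40 measured, 25 were higher and 15 lower in the knockout, with a mean log2 fold change of 0.06 (camera adjusted p = 0.163, and adjusted p = 0.714 with an estimated correlation). None passed when adjusted over the list alone or over all genes. Apaf1, which forms the apoptosome, had a log2 fold change of 0.47, Sesn1 of 0.47 and Ei24 of -0.53. Cdkn1a and Mdm2, which are named here after their values were seen, had log2 fold changes of 0.06 and 0.24 with standard errors of 0.144 and 0.169. The list mean was 0.017 without wild type replicate 3, and its sign turned to -0.0044 without knockout replicate 2. The sign of Cdkn1a turned to -0.0046 without that array and to -0.071 without wild type replicate 3. The list passed upward without wild type replicate 2 (mean 0.12, adjusted p = 0.0359, and adjusted p = 0.703 with an estimated correlation) and without knockout replicate 3 (mean 0.12, adjusted p = 0.0224, and adjusted p = 0.633 with an estimated correlation). The list mean was highest at replicate 2 and lowest at replicate 3 in both genotypes, as in the immediate early and dissociation stress list. Arrays of the same replicate number, compared as pairs after the list values were seen, differed by 0.05, 0.09 and 0.04, each higher in the knockout. Leaving out 1 array breaks such a possible pair. With replicate as a block the adjusted p was 0.0919, and 0.707 with an estimated correlation.

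Interferon response genes were higher in the knockout as a list. Of 41 measured genes 34 were higher and 7 lower, with a mean log2 fold change of 0.46 and a median of 0.42. The mean of the list was 6.74 ± 0.031 (SD, n = 3) in wild type cells and 7.20 ± 0.155 in knockout cells, and each knockout array lay above each wild type array. Of the list, 14 genes passed when adjusted over the list alone, all of them higher, and 0 when adjusted over all genes. Rtp4, a receptor transporter protein induced by interferon, was 2.75 times as high in the knockout, with a log2 fold change of 1.46 and a standard error of 0.233. Ifit1, which binds foreign RNA, was 3.54 times as high, Gbp7, a guanylate-binding protein, 1.91 times, and Xaf1, a pro-apoptotic interferon-induced gene, 2.20 times. Oas1g, a gene of the antiviral oligoadenylate synthetase family outside the list, was dim in wild type cells, at 3.16 ± 0.139 (SD, n = 3), and 5.52 ± 1.07 in knockout cells. None of these 5 genes passed over all genes.

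The list passed camera (adjusted p = 1.12e-16). With an estimated correlation the adjusted p was 0.124, from an unadjusted p of 0.00295, and fry gave an adjusted p of 0.182 for a shift one way and of 0.0184 for change in either direction. The exact two-sided permutation test of the 3 list means against 3 gave 0.1, the smallest value this design allows. The antigen presentation, fibroblast, adipocyte and keratinization lists reached the same value, so it does not single out the interferon list. The interferon list passed camera without any one of the arrays, with means between 0.41 and 0.55. Within each genotype its mean was lowest at replicate 3, at 6.70 and 7.02, as was that of the immediate early and dissociation stress list, at 8.90 and 9.10, which shares 0 members with it.

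**Figure D2:**
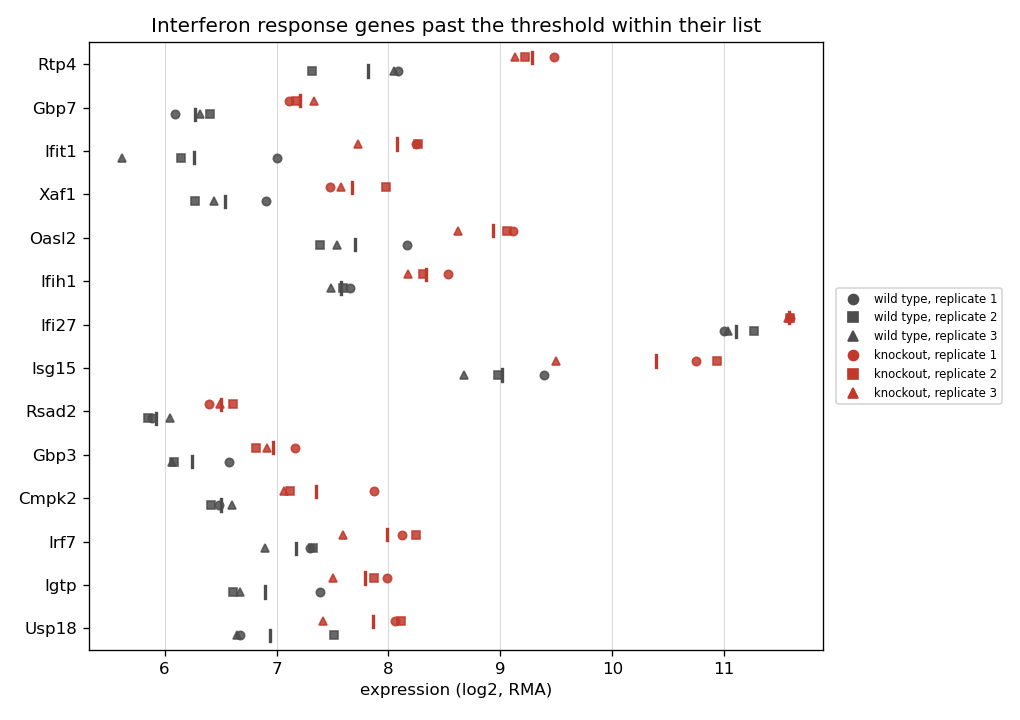
Log2 expression of the 14 interferon response genes that passed when adjusted over their list alone, on each array, with wild type in grey, knockout in red and a bar at each group mean. The groups do not overlap for 13 of these genes, and they were selected for their difference.

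Genes of inflammation and of antigen presentation were also higher as lists, by less. NF-kappaB inflammatory genes had 18 of 28 members higher and a mean log2 fold change of 0.20 (camera adjusted p = 0.00427, and adjusted p = 0.714 with an estimated correlation). Its means were 7.53, 7.60 and 7.24 on the wild type arrays and 7.75, 7.69 and 7.53 on the knockout arrays. They were lowest at replicate 3 in both genotypes, as in the immediate early and dissociation stress list, which shares 0 members and also lost its call without wild type replicate 3. Ccl2, a chemokine that attracts monocytes, had a log2 fold change of 0.75 and the cytokine Il1b of 0.52. Antigen presentation genes had 15 of 19 members higher and a mean of 0.13 (adjusted p = 0.0142, and adjusted p = 0.714 with an estimated correlation). B2m, the light chain of class I molecules, had a log2 fold change of 0.34, and H2-Ab1, a class II chain, of 0.64. Secreted factors associated with senescence, 8 of them also in the NF-kappaB list, had 20 of 30 members higher and a mean of 0.12 (adjusted p = 0.0235, and adjusted p = 0.714 with an estimated correlation), with Mmp3, a matrix protease, at 0.79 and Timp1, an inhibitor of such proteases, at -0.92. None of these 3 lists had a member that passed when adjusted over the list alone. The NF-kappaB list no longer passed without wild type replicate 3 (mean 0.090, adjusted p = 0.388) or knockout replicate 1 (mean 0.15, adjusted p = 0.0569). The antigen presentation list no longer passed without wild type replicate 1 (mean 0.077, adjusted p = 0.398) or knockout replicate 1 (mean 0.087, adjusted p = 0.147). The senescence list no longer passed without wild type replicate 1 or 3 or knockout replicate 1 or 3, with means between 0.077 and 0.14 and adjusted p between 0.0651 and 0.304, nor with all rows of the table (0.0649), the luminal marker level as a covariate (0.228) or camera on ranks (0.0761). Same-numbered arrays, which leaving out 1 array unpairs, differed by 0.22, 0.09 and 0.29 in the NF-kappaB mean and by 0.32, 0.02 and 0.05 in the antigen presentation mean, but by -0.0070 in the senescence mean at replicate 2. Array weights moved the NF-kappaB mean to 0.33.

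Immediate early and dissociation stress genes, known for rapid induction, had 27 of 33 members higher in the knockout, with a mean log2 fold change of 0.27 (camera adjusted p = 9.7e-05, and adjusted p = 0.714 with an estimated correlation). No member passed when adjusted over the list alone. Hspa1b, a heat shock protein, had a log2 fold change of 0.38, the nuclear receptor Nr4a2 of 0.62 and Ppp1r15a of 0.70. The list means of the arrays were 9.35, 9.57 and 8.90 in wild type cells and 9.57, 9.97 and 9.10 in knockout cells, so same-numbered arrays differed by 0.22, 0.40 and 0.19, each higher in the knockout. With replicate as a block the adjusted p was 9.89e-12, and with the block and an estimated correlation the adjusted p was 0.707. Whether the numbers pair the arrays is not known. The list no longer passed without wild type replicate 3 (mean 0.09, adjusted p = 0.388) or knockout replicate 2 (mean 0.06, adjusted p = 0.459), where leaving out 1 array would break such a pair. Its mean was 0.42 without wild type replicate 2, 0.50 without knockout replicate 3 and 0.45 with array weights.

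Luminal epithelial markers were lower in the knockout on average, with overlapping arrays, although the cells were sorted as basal. General luminal markers had 17 of 18 members lower and a mean log2 fold change of -0.35 (camera adjusted p = 0.000149, and adjusted p = 0.714 with an estimated correlation). Anxa3 had a log2 fold change of -0.48, the luminal keratin Krt18 of -0.61 and Wfdc2 of -0.90. Markers of hormone-sensing luminal cells had 18 of 21 members lower and a mean of -0.42 (adjusted p = 7.1e-05, and adjusted p = 0.714 with an estimated correlation), with Fgg at -1.25, Stc2 at -0.62 and Sytl2 at -0.85. No member of either list passed when adjusted over the list alone. The general luminal list means were 8.23, 9.21 and 8.99 on the wild type arrays and 8.53, 8.65 and 8.22 on the knockout arrays, so wild type replicate 1 lay within the knockout range. Same-numbered arrays differed by 0.30, -0.56 and -0.77 in this list and by 0.21, -0.60 and -0.88 in the hormone-sensing list. Without wild type replicate 2 neither list passed, with means of -0.14 (adjusted p = 0.173) and -0.23 (adjusted p = 0.0755). Without wild type replicate 1 the means were -0.63 and -0.74, and the general luminal mean was -0.22 without knockout replicate 3. With the general luminal level as a covariate, itself lower in the knockout, the hormone-sensing list no longer passed (mean -0.061, adjusted p = 0.612). Since the covariate holds part of the genotype difference, this loss cannot tell what lowered the list.

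Markers of the basal layer itself did not pass. Of 28 measured, 13 were higher and 15 lower, with a mean log2 fold change of 0.02 and a median of the other sign, -0.01 (camera, upward, adjusted p = 0.838). The mean turned to -0.024 without wild type replicate 3 and to -0.054 without knockout replicate 2. Krt14, the basal keratin, was 13.4 ± 0.122 (SD, n = 3) in wild type cells and 13.3 ± 0.039 in knockout cells. Trp63, the basal lineage transcription factor, had a log2 fold change of 0.35 and the myosin Myh11 of 0.23. Mammary stem cell associated genes had 19 of 26 members higher and a mean of 0.12 (adjusted p = 0.0688, and adjusted p = 0.714 with an estimated correlation), with the Wnt target Axin2 at 0.82 and Gng11 at 0.48. That list passed without wild type replicate 2 (mean 0.13, adjusted p = 0.0466) or knockout replicate 3 (mean 0.16, adjusted p = 0.0199), calls lost with an estimated correlation (adjusted p = 0.703 and 0.633). Its mean was 0.065 without wild type replicate 3 (adjusted p = 0.544) and 0.068 without knockout replicate 2. Luminal progenitor markers had a mean of 0.06 and a median of the other sign, -0.02 (camera, upward, adjusted p = 0.730), with Csn3 at 0.84, Lalba at 1.94 and Aldh1a3 at -0.30. That mean lay between 0.0092 without knockout replicate 3 and 0.16 without wild type replicate 2 or knockout replicate 2, and was at most 0.023 without any one of the other arrays.

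Mitosis genes were lower in the knockout as a list, a call lost without 1 of the arrays. G2/M and mitosis genes had 30 of 33 members lower and a mean log2 fold change of -0.31 (camera adjusted p = 3.9e-05, and adjusted p = 0.714 with an estimated correlation). Anln, a cytokinesis protein, had a log2 fold change of -0.80, Birc5 (survivin) of -0.74 and the spindle checkpoint kinase Bub1b of -0.26, and no member passed when adjusted over the list alone. The list means were 5.57, 5.07 and 6.23 on the wild type arrays and 5.12, 5.31 and 5.52 on the knockout arrays, so same-numbered arrays differed by -0.46, 0.24 and -0.71. Without wild type replicate 3 the mean was -0.0084 (adjusted p = 0.871), without wild type replicate 2 it was -0.58, and with array weights -0.66. The log2 fold change of Anln was -0.29 and that of Birc5 -0.19 without wild type replicate 3. E2F target and DNA replication genes had 23 of 32 members lower and a mean of -0.10 (adjusted p = 0.0862), with Mcm6, part of the replicative helicase, at -0.51 and Rbl1 at -0.54. Same-numbered arrays differed by 0.04, 0.05 and -0.39 in that list. Its mean was -0.20 with array weights and -0.051 with the general luminal level as a covariate. Without wild type replicate 3 that mean was 0.011, and the list passed downward without wild type replicate 1 (mean -0.16, adjusted p = 0.0181) or wild type replicate 2 (mean -0.16, adjusted p = 0.00747), calls lost with an estimated correlation (adjusted p = 0.640 and 0.703). Cyclin-dependent kinase inhibitors and RB pathway genes had 10 of 17 members higher and a mean of 0.05 (adjusted p = 0.301), with Cdkn1c (p57) at 0.46 and the cyclin Ccnd1 at -0.58. Its sign turned without wild type replicate 1 or knockout replicate 2, to -0.0096 and -0.05, and its mean was 0.10 without wild type replicate 2 and 0.13 without knockout replicate 3. With the general luminal level as a covariate its mean was 0.15 (camera adjusted p = 0.0266, and adjusted p = 0.841 with an estimated correlation).

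Oxidative phosphorylation genes had 26 of 30 members lower and a mean log2 fold change of -0.12 (camera adjusted p = 0.0143, and adjusted p = 0.714 with an estimated correlation). Sdha, of respiratory complex II, had a log2 fold change of -0.42 and Cox5a, of complex IV, of -0.18, and no member passed when adjusted over the list alone. The list means were 9.71, 10.07 and 10.11 on the wild type arrays and 9.83, 9.90 and 9.81 on the knockout arrays. Wild type replicate 1 thus lay below every knockout array, and same-numbered arrays differed by 0.12, -0.17 and -0.30. Wild type replicate 1 and knockout replicates 1 and 3 had the lowest means, as in the general luminal list. The list no longer passed without wild type replicate 2 or 3 or knockout replicate 1 or 3, with adjusted p between 0.0727 and 0.815. Its mean was -0.062 without wild type replicate 2, -0.043 without wild type replicate 3, -0.24 without wild type replicate 1, -0.18 with array weights and 0.012 with the luminal level as a covariate, which turned the sign. In all, 9 of the 42 lists passed camera, 5 upward and 4 downward. With an estimated correlation 0 passed, and fry called 0 for a shift one way. Apart from the interferon list, the lists past camera tied at an adjusted p of 0.714 with an estimated correlation. Their unadjusted camera p then lay between 0.0615 for antigen presentation and 0.399 for oxidative phosphorylation. The exact two-sided permutation p of the list means was 0.1 for the interferon and antigen presentation lists. For the other lists past camera it lay between 0.3 and 0.5. Without wild type replicate 3 only 4 lists passed camera and without knockout replicate 1 only 5.

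**Figure D3:**
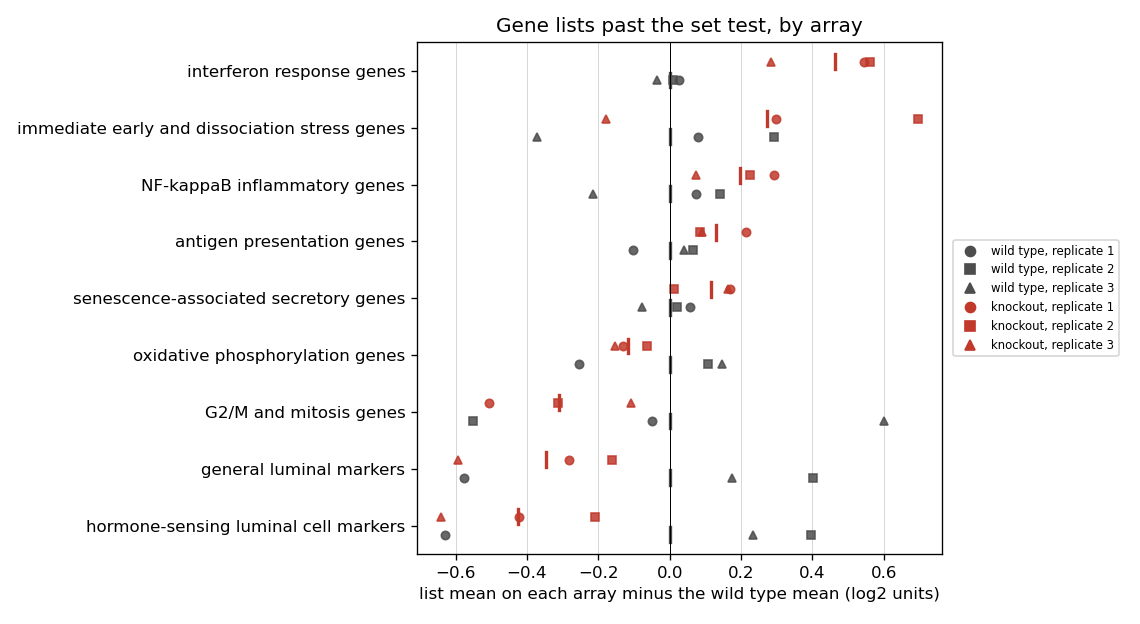
Mean of each of the 9 lists past camera on each array, minus the wild type mean of that list, in log2 units, with wild type in grey, knockout in red, a marker shape per replicate number and a bar at each group mean. The interferon and antigen presentation lists are the only ones of the 9 whose knockout arrays all lie above all wild type arrays, and in no list do all knockout arrays lie below.

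Marker lists of cells outside the epithelium that a basal sort could hold did not pass camera under the settings used for the comparison, but the fibroblast list passed in 5 of 16 alternatives. Fibroblast markers had 20 of 29 members higher and a mean of 0.15 (adjusted p = 0.0554, and adjusted p = 0.714 with an estimated correlation). The list means were 6.86, 6.85 and 6.70 on the wild type arrays and 6.93, 6.97 and 6.96 on the knockout arrays, all of the latter above all of the former (exact two-sided permutation p = 0.1). The adjusted p was 0.0386 with a constant prior variance, 0.0493 with median centring, 0.0293 with the mean of a gene's rows, 0.0142 without the dimmest 40% of genes and 0.0423 with replicate as a block. With an estimated correlation the adjusted p of these 5 fits lay between 0.671 and 0.707, the latter with the block. The fibroblast mean was 0.095 without wild type replicate 3 (adjusted p = 0.304). For change in either direction fry gave adjusted p of 0.0348 for this list and 0.0184 for the endothelial and adipocyte lists. Adjusted over the list alone, 3 of its members passed, Dpt and Lum, both of the collagen matrix, at 1.21 and 1.28, and Ly6c1 at -0.94. Dcn, a matrix proteoglycan with a wild type level of 11.4, had a log2 fold change of 0.54. Endothelial markers had a mean of 0.11 (adjusted p = 0.0600), which passed without wild type replicate 1 (mean 0.18, adjusted p = 0.0122, and adjusted p = 0.408 with an estimated correlation) and was 0.072 without wild type replicate 2 (adjusted p = 0.420). Adipocyte markers had a mean of 0.12 (adjusted p = 0.0688). Their list means were 5.86, 5.92 and 5.84 on the wild type arrays and 5.99, 6.06 and 5.93 on the knockout arrays, all of the latter above all of the former (exact two-sided permutation p = 0.1). Fabp4, a fatty acid carrier that both of these lists hold, passed when adjusted over each list alone. Ptprb was at 0.42, Cd36 at 0.37 and Cidea at -0.37. Carry-over of fibroblasts, endothelial cells or adipocytes was not tested. Macrophage and myeloid markers had 16 of 26 members higher and a mean of 0.07 (adjusted p = 0.30), with Ctss, a lysosomal protease, at 0.71 and S100a9 at -0.49. The myeloid list passed without knockout replicate 2 (mean 0.13, adjusted p = 0.0295, and adjusted p = 0.650 with an estimated correlation), and its mean was 0.028 without knockout replicate 3, 0.035 without knockout replicate 1 (adjusted p = 0.687) and 0.044 without wild type replicate 3.

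The 10 genes of smallest p among those with knockout above wild type on every array were Fabp4, Speer8-ps1, Rtp4, Dpt, Gbp7, Ifit1, Oas1g, Sparcl1, Speer4c and Xaf1, and none of them passed. Their log2 fold changes lay between 0.94 and 2.37. Fabp4 had the smallest p, with 8.14 ± 0.094 (SD, n = 3) in wild type cells and 9.44 ± 0.259 in knockout cells, a log2 fold change of 1.31 with a standard error of 0.179 (limma adjusted p = 0.818). In the other direction they were Ly6c1, Naip6, Cln8, Taar8a, Rab15, Zfp943, Mid1, Lrrc74b, Mup20 and Msr1, and none passed. Their log2 fold changes lay between -1.16 for Mid1, a microtubule-associated ubiquitin ligase, and -0.49 for Taar8a. Ly6c1, Taar8a, Mup20 and Msr1 had wild type levels between 3.44 and 4.10, below the medians of the arrays.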

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

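The luminal covariate, an estimated correlation in each alternative and the lists without shared interferon genes were chosen after seeing the data. The counts of higher and lower genes were 0 under each alternative prior, weighting, normalization, filter, choice of rows, covariate and the replicate block, at an adjusted p under 0.05 with or without a 2-fold minimum and under 0.10, and without each array (lowest and highest 0). At an unadjusted p under 0.05 with a 2-fold minimum 20 genes were higher and 16 lower, a looser threshold by construction. The count of 9 lists fell to 0 with an estimated correlation, and to 0 with the replicate block and an estimated correlation. Without the block, the estimates for these 9 lists lay between 0.0357 for antigen presentation and 0.629 for immediate early genes, all above the preset 0.01. A larger correlation raises the p of camera, but the p also rose for lists with estimates below 0.01. The fibroblast estimate was -0.0073, and the unadjusted camera p went from 0.0132 to 0.0486. For the adipocyte list the estimate was -0.048, and that p went from 0.0214 to 0.0692. A larger correlation alone thus does not account for the rise, and no separate test of the loss was run. With the replicate block at the preset correlation 10 passed, which added the fibroblast list, and pairing changed no other call. Without each array in turn between 4 and 12 lists passed, with 4 without wild type replicate 3 and 5 without knockout replicate 1. Under the remaining alternatives with camera 8 to 13 passed, and fry called 0 for a shift one way. The Cdkn2a log2 fold change of 0.07 turned to -0.0679 with array weights and to -0.0640 with the luminal covariate, and lay between -0.13 and 0.19 without each array. The cause was not tested. Oxidative phosphorylation genes turned to 0.0124 with the luminal covariate, where the cause was not tested. Leaving out 1 array turned the sign of basal markers (-0.0543 to 0.0768), Cdkn1a (-0.0713 to 0.18), kinase inhibitor and RB pathway genes (-0.0505 to 0.13), E2F targets (-0.16 to 0.0110) and p53 targets (-0.0044 to 0.12), none of which passed in the full comparison. The luminal covariate brought p53 targets, kinase inhibitor and RB pathway genes and smooth muscle contractile genes (each adjusted p = 0.0266) and keratinization genes (0.00305) past the threshold in camera, calls lost with an estimated correlation (adjusted p = 0.841, and 0.790 for keratinization). Array weights brought E2F targets (0.000584), histone genes (0.00330) and stem cell genes (0.0121), each with adjusted p = 0.466 with an estimated correlation. Leaving out the dimmest 40% of genes brought E2F, stem cell, fibroblast and myeloid lists (0.0142 to 0.0413), with adjusted p of 0.671 to 0.710 with an estimated correlation. A constant prior variance, median centring and the mean of a gene's rows each brought the fibroblast list. Histone genes also passed without wild type replicate 2 (0.0359) or knockout replicate 2 (0.00736), cholesterol and fatty acid synthesis genes without wild type replicate 1 (0.00825) and smooth muscle contractile genes without knockout replicate 3 (0.0345). With an estimated correlation 0 lists passed in any of the 17 fits, where the smallest adjusted p was 0.0669. Without genes shared with the interferon list, the antigen presentation (adjusted p = 0.0176) and NF-kappaB (0.00591) lists passed, and each had adjusted p = 0.714 with an estimated correlation. The senescence list shared none. Leaving out 1 array moved the log2 fold change of 31 of 76 named genes by over 1.5 times. No named gene crossed the threshold under any alternative run. Trp53 had no row under its own symbol and was not run. How far dim genes lie above background is not known here, and fold changes near the floor are the least certain.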

Other observations

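The tests of immune and luminal carry-over and the interferon shift over other splits were chosen after the result was seen. Apart from the 22 lists given individually in the report and here, the other 20 tested lists, epithelial-mesenchymal transition genes among them, had camera adjusted p between 0.163 and 0.976 and means between -0.15 and 0.09. Canonical Wnt targets had 18 of 26 members higher and a mean log2 fold change of 0.10 (adjusted p = 0.163), with Axin2 at 0.82 and Sfrp2, a secreted Wnt modulator, at 0.58, and passed without knockout replicate 3 (mean 0.16, adjusted p = 0.0319, and adjusted p = 0.633 with an estimated correlation). The Wnt mean was 0.045 without knockout replicate 2 and 0.055 without wild type replicate 3 (adjusted p = 0.664). Keratinization genes had 21 of 29 members lower and a mean of -0.14 (adjusted p = 0.0677), with Krt6a at -1.08 and Sfn at -0.55, and passed without wild type replicate 2 (adjusted p = 0.0359) or knockout replicate 3 (0.0167), calls lost with an estimated correlation (adjusted p = 0.703 and 0.633). All knockout means of this list lay below all wild type means (exact two-sided permutation p = 0.1), and same-numbered arrays differed by -0.16, -0.19 and -0.06.

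Milk protein genes had a mean of 0.31 but a median of 0.05 (adjusted p = 0.219), and their list means were 6.24, 5.85 and 6.78 on the knockout arrays against 5.99, 5.98 and 5.97 in wild type cells. The list passed without knockout replicate 2 (mean 0.53, adjusted p = 0.00132, and adjusted p = 0.404 with an estimated correlation), and its mean was 0.060 without knockout replicate 3 (adjusted p = 0.939). Lalba, part of lactose synthase, read 9.47, 6.72 and 9.69 on the knockout arrays and 7.38, 6.82 and 5.87 on the wild type arrays. Among epithelial-mesenchymal transition genes, Twist1, a mesenchymal transcription factor, was at 0.82 and passed when adjusted over the list alone but not over all genes, and Prrx1, at 0.62, passed neither.

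The 6 arrays make 10 splits into 3 and 3, the real one included, too few for a share under 0.05. The real split gave 0 genes past the threshold, as did all 10, with the highest other at 0. It gave 9 lists past camera, 5 splits gave at least as many, and the highest other gave 15. Wild type replicate 1 with knockout replicates 1 and 3 against the remaining arrays gave 2595 genes at an unadjusted p under 0.05. The real split gave 736, which points to a structure of the arrays other than genotype. The former 3 arrays also had the lowest general luminal means, at 8.23, 8.53 and 8.22. These means were 9.21 and 8.99 on wild type replicates 2 and 3 and 8.65 on knockout replicate 2. The first principal component, the direction of largest variance, held 37.9% of it and parted the same arrays. What sets this structure was not tested. Among the 4 splits that part every same-numbered pair, those other than the real one gave 6 to 9 lists, 494 to 954 such genes and interferon shifts of up to 0.25. Each split outside these 4 parted 1 pair.

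Interferon response genes were higher in the knockout by a mean of 0.463, a size that 1 of 10 splits reached, the real one, with the highest other at 0.290. Immune cells that escaped the depletion of CD45 cells may bring such transcripts, and 22 immune markers above the dimmest 40% of genes, none of them in the interferon or antigen presentation lists, had a mean log2 fold change of 0.0796 with a 95% interval of -0.120 to 0.279 over the arrays. All 58 such markers had a mean of 0.0240 with an upper bound of 0.204, below the bound of 0.232 set for this test, which is the interferon mean divided by 2, while the upper bound of the 22 brighter ones is above it. The brightest of them were Cd14, which the luminal progenitor list also holds, at 7.59 in wild type and 7.41 in knockout cells, Ighm, at 7.27 and 7.20, and Cd68, at 7.15 and 7.51, picked for their level, and the 19 brighter markers that no other list holds had a mean of 0.0926 with an upper bound of 0.321. Immune carry-over stays open, as do an effect of genotype and a difference in the animals' exposure, neither of which was tested.

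Luminal markers were lower in the knockout on average, with overlapping arrays. Luminal cells carried over the CD49f and CD24 gate in differing amounts between arrays may account for it. General luminal markers moved together within groups, with an estimated correlation of 0.578, but so did mitosis genes at 0.611 and immediate early genes at 0.629, so this does not single out carry-over. Krt18, an abundant luminal keratin, was at 11.62 ± 0.636 (SD, n = 3) in wild type and 11.01 ± 0.345 in knockout cells. Wild type replicate 1 lay within the knockout range, and luminal progenitor markers had a mean of 0.06, between 0.0092 and 0.16 without 1 array, where hormone-sensing markers had -0.42. Differing amounts of carry-over and lower expression of these markers in the sorted knockout cells cannot be told apart. Either could give lower values in the knockout.

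Among 15 measured Speer genes, a repeated family known from testis, 6 had all knockout arrays above all wild type arrays and an unadjusted p under 0.05, Speer4d with a log2 fold change of 2.37, and Nnt, which is partly deleted in the C57BL/6J strain, was at 0.89, all picked out after their values were seen. A candidate explanation for these and for the Cdkn2b value of 0.44 is a difference in strain background. Outside these genes and the interferon list, the 100 genes of smallest p held 3 neighbouring pairs with the same direction, against a median of 1 in 10000 random draws (permutation p = 0.1045). The 25 genes on each side of Trp53 and of Cdkn2a lay at the 39.4th and 90.1st percentile of random windows in mean absolute moderated statistic. These windows left out only the targeted gene itself, so that of Cdkn2a held Cdkn2b, whose value was to be explained. Neither test settles it, strains are not given in the sources used here, and probes shared between near-identical Speer copies also stay open.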
